A study of Mus musculus with 10 samples.

How the data were processed

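Total RNA of whole lung from 10 male C57BL/6 mice aged 6 to 8 weeks was measured on Affymetrix Mouse Genome 430A 2.0 arrays, 1 array per animal, 5 in normoxia and 5 in intermittent hypoxia, per the labels. The values were log2 probe set levels as deposited by the authors, and RMA and affy are named per the submitters' processing notes, without versions or settings. The standard deviation of the arrays ran from 1.89 to 2.05, a wider range than quantile normalization over all 10 arrays together would be expected to leave, so how the arrays were normalized is uncertain, and with it the share of changed probe sets that were higher (71.2%, or 59.1% after quantile normalization here). The log2 scale was checked on the values, and the median of the 10 arrays lay between 7.69 and 7.73. The table held 0 AFFX control probe sets, and all 22626 probe sets were tested without a filter. The number of arrays limits the precision of the comparison.

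Probe sets were named from the array's annotation table, which gave 1 symbol for 20380 of them, several for 691 and none for 1555. Of those with 1 symbol, 20351 had an Entrez identifier in the reference gene table and 0 symbols were updated through it. For gene lists and named genes, each of 12393 genes was represented by its probe set with the highest mean over all arrays, chosen without regard to group.

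Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The p-values reflect the spread between animals. Gene lists were compared with camera at its preset correlation of 0.01, adjusted over the tested lists. Of 44 fixed lists 43 were tested, and the list of cold-inducible RNA-binding proteins was left out because it had fewer than 4 measured genes. The count "adjusted over the list alone" repeats the adjustment with only that list's members. A list score was the mean of the members' log2 values after centring each gene over the arrays.

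Named genes followed a fixed rule. In each direction these were the 12 genes with the largest absolute log2 fold change among those that passed, and beside them up to 4 members with the smallest p of each passing list and up to 2 of each other list. Transcripts with clone names were passed over, and names outside the rule are marked in the text. Not every gene that the rule allows was named.

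The following alternatives were planned: SAM with 100 permutations, which the series' design text names, a replicate block, quantile normalization, arrays centred on their medians, only probe sets at or above the median level, eBayes with trend and robust options, arrayWeights, an adjusted p below 0.10, the mean of all probe sets of a gene, leaving out each array in turn, camera with an estimated correlation, and fry. Leaving out normoxia arrays 2 to 4 together and an exact permutation test of list scores were added after the data were seen. Replicate numbers were checked for pairing by correlating the deviations of arrays with the same number. The tools were tested on simulated data of 22626 probe sets with independent noise, so effects shared across an array were not covered. Besides a log2 shift of 0.3 in the rest of the matrix list, 200 probe sets were changed. Of those changed by 0.5 on the log2 scale limma recovered 79%, and of those changed by 1 it recovered 98%, with 4.21% of its 190 calls on unchanged genes. SAM recovered 75% and 98%, with 3.28% false among 183 calls.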

Results

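Gene expression was measured in the whole lung of adult male C57BL/6 mice, a common inbred strain, aged 6 to 8 weeks. Of 10 lungs, 5 came from mice breathing room air (normoxia) and 5 from mice exposed to intermittent hypoxia, in which the oxygen of the inspired air falls and recovers again and again. Each lung was measured on its own Affymetrix Mouse Genome 430A array, so 5 arrays stood in each group, and the series' design text calls them separate animals. The oxygen levels, the length of the exposure and the hour of tissue collection were not given in the sources used here. The table held log2 values of 22626 probe sets, of which 20380 carried 1 gene symbol, 691 carried several and 1555 were unnamed here. Values ran from about 4 to 15 on the log2 scale, array medians lay between 7.69 and 7.73, and the number of arrays limits the precision of every comparison. Correlations between 2 arrays over all probe sets ranged from 0.982 to 0.996, and no pair of arrays held identical values. Normoxia arrays 1 and 5 had higher mean correlations with the hypoxia arrays (0.994 and 0.993) than with the other normoxia arrays (0.993 and 0.991). Every other array correlated better with its own group. The standard deviation over the probe sets of an array was 1.89 to 1.93 on normoxia arrays 2, 3 and 4 and 1.99 to 2.05 on the other 7. By group it was 1.95 ± 0.05 in normoxia and 2.02 ± 0.02 in intermittent hypoxia (SD, n = 5 each; exact two-sided permutation p = 0.0476).

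The series' title concerns chronic intermittent hypoxia and the alveolar surface of the adult lung, and the comparison asked which transcripts differed between exposed and control lungs. Lists of extracellular matrix genes and of fatty acid and cholesterol synthesis were higher after intermittent hypoxia. So were the lists of dendritic cell and MHC class II genes and of B and plasma cell markers. A list of glucocorticoid-responsive transcripts was lower, and genes of the circadian clock moved in both directions. These 5 list calls used camera's preset correlation and were lost when the correlation was estimated, with adjusted p values from 0.0596 for the glucocorticoid list to 0.623 for the B cell list, and the clock list did not pass. Counted with 1 probe set per gene, the largest rise was that of Nr1d1, which encodes the clock repressor REV-ERBα, from a log2 level of 7.76 ± 0.28 to 10.05 ± 0.51 (SD, n = 5), or 4.88-fold. Among genes past the limma test on this count, the largest fall was that of Pdk4, a kinase that restrains pyruvate oxidation. Pdk4 dropped by 1.50 on the log2 scale (SE 0.33) to 0.354 of its normoxia level. On the same count the smallest adjusted p among falls was that of Angptl4, a secreted inhibitor of lipoprotein lipase, which fell by 1.21 (SE 0.10) to 0.431 of its normoxia level, and it shared this p of 9.3e-05 with the rise of Emcn.

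At a limma adjusted p below 0.05, 2699 probe sets (11.9%) changed, 1923 higher and 776 lower after intermittent hypoxia. Most changes were small. The median absolute log2 fold change of the changed probe sets was 0.39 (1.31-fold), 501 higher and 187 lower ones reached 0.5, and 29 in each direction reached 1. Counted with 1 probe set per gene, 1107 of 12393 genes were higher and 446 lower. Of the changed probe sets 71.2% were higher, a share that quantile normalization moved to 59.1%. The groups did not overlap at all in 1853 probe sets (8.19%), against an average of 0.794% over all possible splits of the arrays. As probe sets on the same arrays vary together, a single split can lie far from this average. The range of the share over splits was not measured.

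The number of changed probe sets depended on single arrays. It was 1341, 1123 and 1003 without normoxia array 2, 3 or 4, 1265, 1383, 1371 and 1714 without hypoxia array 1, 2, 3 or 4, and 4800 without normoxia array 5. Without normoxia arrays 2, 3 and 4 together, a choice made after seeing their narrow spread, 16 probe sets passed, and leaving out any 3 normoxia arrays gave 12 to 6255. Of 109 genes that the naming rule picked and the test passed, 7 kept their calls without these 3 arrays. The named probe sets among the 16 belonged to Nr1d1, Emcn, Loxl1, Gja1 and Pdgfb, which were higher, and to Ivd, Hspa2, Gdpd1, Cry1, Tle1, Slc4a1 and Angptl4, which were lower. Of these, Gja1, Ivd, Hspa2, Gdpd1 and Tle1 were named after their values were seen.

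Next to Nr1d1, the genes with the largest rises among those past the test were a mixed set. Dbp, a transcription factor of the clock output, rose by 2.09 on the log2 scale (SE 0.43, limma adjusted p = 0.0130). Plac8, expressed in several leukocytes, rose by 1.40 (SE 0.21) and Hs2st1, a heparan sulfate sulfotransferase, by 1.35 (SE 0.17). The matricellular protein gene Thbs1 rose by 1.25 (SE 0.23) and Aplnr, the apelin receptor of endothelial cells, by 1.15 (SE 0.21). The immunoglobulin gene Ighv14-2 rose by 1.23 and the B cell genes Ms4a1 (CD20) and Cd79b by 1.14 and 1.12, and the interferon-induced GTPase genes Gbp6 and Iigp1 rose by 1.12 and 1.08. All of these kept their calls when any single array was left out. Without normoxia arrays 2 to 4 together none of these genes after Nr1d1 passed, with 2 normoxia arrays left. Their limma adjusted p values then ran from 0.0573 for Hs2st1 to 0.367 for Gbp6. The change of Dbp was then 2.16, and those of the others ran from 0.66 for Cd79b to 1.04 for Hs2st1. Ttr, the carrier of thyroid hormone and retinol, rose by 1.48 (SE 0.44, limma adjusted p = 0.0475), but lost its call without any of 7 single arrays, normoxia arrays 2 to 5 and hypoxia arrays 1, 2 and 4, with adjusted p values up to 0.108. It also lost it with SAM (0.0743), with quantile normalization (0.0562), with eBayes trend and robust options together (0.114) and with the mean of the gene's probe sets (0.0502).

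Among the 12 largest falls that passed the test, 6 stood on the glucocorticoid or clock lists described below. Ltf, the secreted iron-binding protein lactoferrin, fell by 1.19 (SE 0.24, limma adjusted p = 0.0118), and Adamts15, a matrix protease, fell by 1.05 (SE 0.13, adjusted p = 0.00178). Falls of 1.25, 1.18, 1.11 and 1.10 were measured for Casq1 and Trdn, which take part in calcium release in muscle, for the amino acid oxidase Il4i1 and for the protease Bace2. These 4 genes each lost the call without any of 7 single arrays, normoxia arrays 2 to 4 and hypoxia arrays 1 to 4, with adjusted p values up to 0.0949 for Casq1, 0.0780 for Trdn, 0.101 for Il4i1 and 0.0925 for Bace2. With SAM their adjusted p values were 0.0638, 0.0565, 0.0652 and 0.0627, and with eBayes trend and robust options together 0.0889, 0.0737, 0.0879 and 0.0815. All 4 were high on normoxia arrays 2 to 4, and without these arrays their changes were -0.26, -0.40, -0.38 and -0.38. Of 5 other probe sets of Trdn none passed, the mean of its probe sets did not pass (adjusted p = 0.168), and 1 of 2 other probe sets of Bace2 had the opposite sign.

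**Figure D1:**
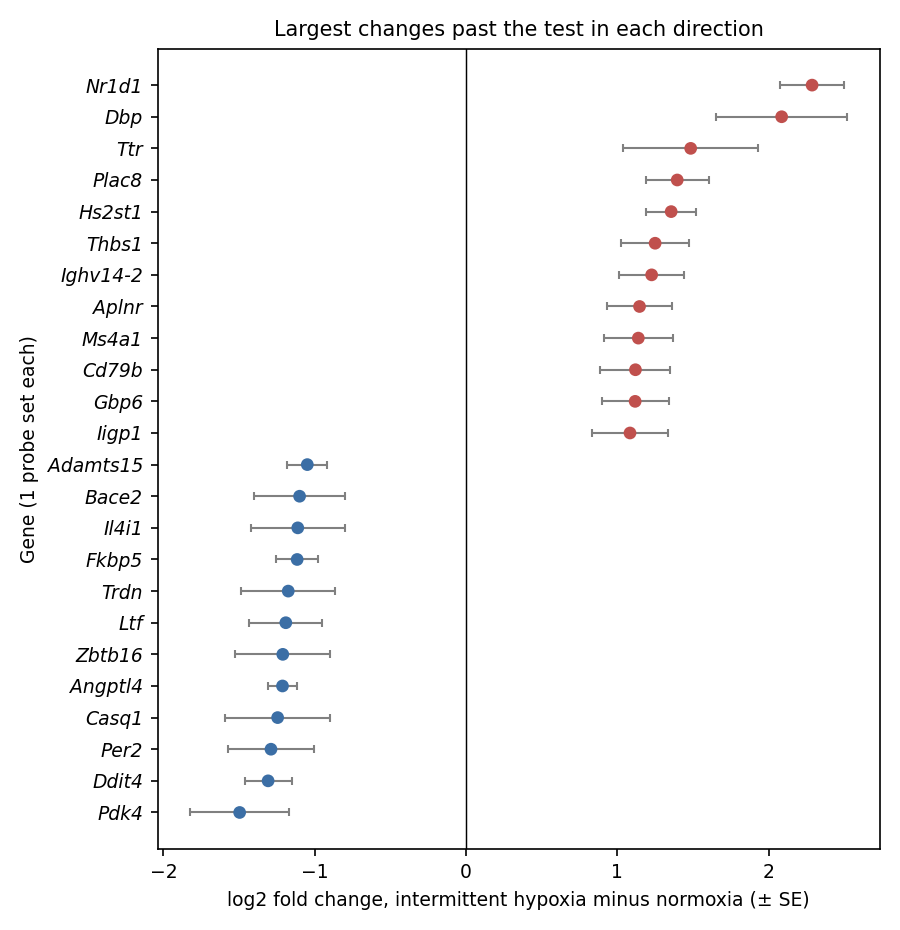
Log2 fold change (horizontal axis, intermittent hypoxia minus normoxia, n = 5 arrays per group) of the 12 genes with the largest changes in each direction among those past the limma test. Points are estimates and bars are standard errors, and Nr1d1 at 2.29 and Pdk4 at -1.50 mark the ends.

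Genes of the circadian clock and its output moved apart. On this list Nr1d1, Dbp and Bhlhe40 rose and Per2, Cry1, Hlf and Usp2 fell, while 12 of 19 members did not pass. Hlf (-0.48, SE 0.10) and Usp2 (-0.40, SE 0.12) were named after their values were seen, and so was Arntl below. Usp2 lost its call without any of 6 single arrays, normoxia arrays 2 to 4 and hypoxia arrays 1, 4 and 5, at adjusted p values up to 0.107. Bhlhe40, a transcriptional repressor within the clock, rose by 0.44 (SE 0.08, limma adjusted p = 0.00915). The negative-arm genes Per2 and Cry1 fell by 1.29 (SE 0.28) and by 0.93 (SE 0.10), with adjusted p values of 0.0159 and 0.00106. The other probe set of Per2 differed by -0.30 and did not pass. The activator gene Arntl, which encodes BMAL1, differed by -0.06 (SE 0.27, adjusted p = 0.898), but it varied widely within the groups. On the hypoxia arrays it ran from 7.72 to 9.32, in the reverse order of Dbp, which ran from 7.73 to 10.56. Normoxia array 5 had the highest Arntl value of all arrays (9.40) and the lowest of Dbp (6.51). Adjusted over the list alone, 4 members were higher and 5 lower. As the members moved in opposite directions, the list's median of -0.22 and mean of 0.01 differed in sign, and camera gave an adjusted p of 0.0655, which fell to 0.0428 without hypoxia array 2, 0.0200 without hypoxia array 3 and 0.0479 with arrayWeights.

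**Figure D2:**
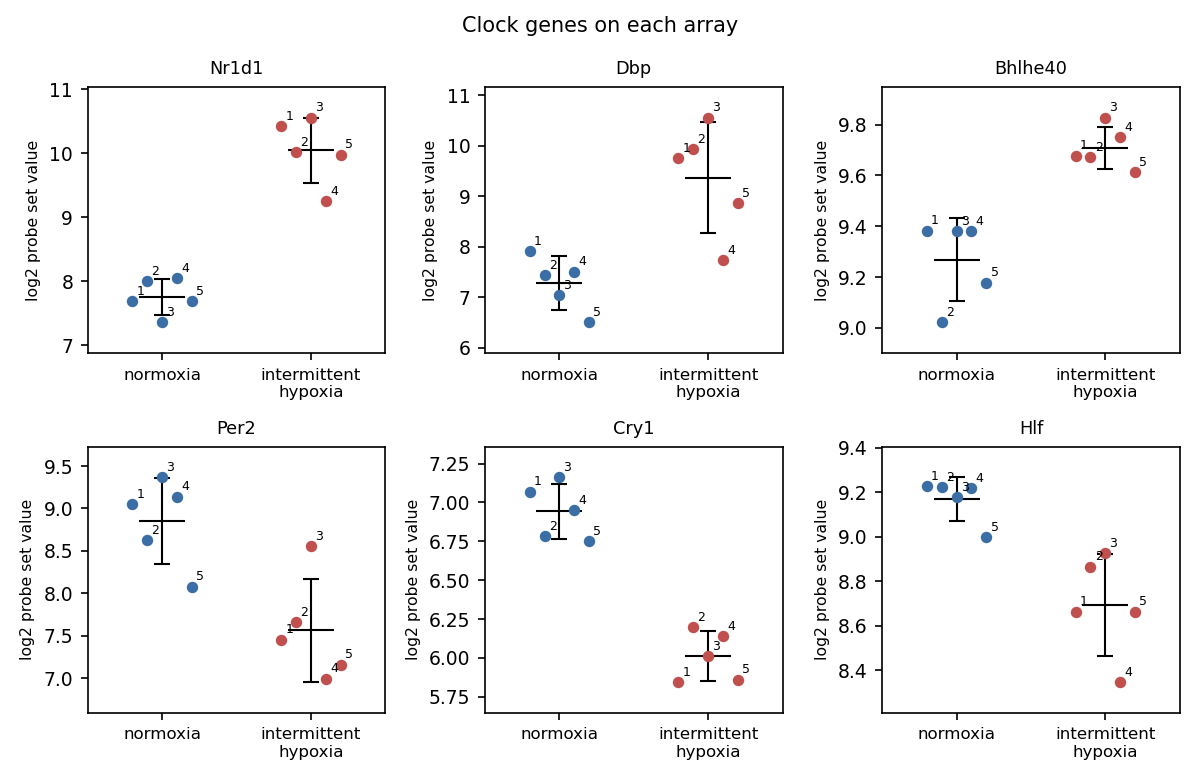
Log2 probe set values (vertical axes) of 6 clock genes on each of the 10 arrays, with replicate numbers beside the points and mean ± SD in black. Nr1d1 lies between 9.25 and 10.55 on the 5 hypoxia arrays and below 8.05 on the 5 normoxia arrays, and the groups of Cry1 are also apart.

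The list with the smallest camera p held 21 genes that glucocorticoid hormones induce in many tissues. Of these 13 fell, none rose and 8 did not pass, and 17 were lower when adjusted over the list alone. The hormone-receptor chaperone gene Fkbp5 fell by 1.12 (SE 0.14) to 0.462 of its normoxia level, and the stress-response gene Ddit4, an inhibitor of mTOR signalling, fell by 1.31 (SE 0.16) to 0.404. Hif3a, a hypoxia-inducible factor subunit, fell by 0.51 (SE 0.06). Pdk4, Angptl4 and the transcription factor gene Zbtb16, which dropped by 1.21 (SE 0.31, limma adjusted p = 0.0288), were also members, and Zbtb16 lost its call without normoxia array 2, 3 or 4 or hypoxia array 3, with adjusted p values up to 0.0743. SAM gave it 0.0545, and eBayes with trend and robust options together 0.0699. The median log2 fold change of the list was -0.43, and the score of every hypoxia array lay below that of every normoxia array. Camera with its preset correlation gave an adjusted p of 5.3e-12, against an adjusted p = 0.0596 with an estimated correlation. Adipose transcripts, which can reach a lung sample with attached fat, were lower as well. All 13 measured members of that list had a negative change, with a median of -0.43, though only 2 fell, Lpl by 0.49 (SE 0.12) and Retn by 0.35 (SE 0.10), and 5 were lower when adjusted over the list alone. Camera gave the adipose list an adjusted p of 0.000139, against an adjusted p = 0.397 with an estimated correlation. Its score was spread widely within both groups, from -0.11 to 0.66 in normoxia and from -0.69 to 0.01 in intermittent hypoxia. Lpl lost its call without normoxia array 4 or hypoxia array 3 (adjusted p up to 0.0531), and Retn without any of 8 single arrays, all but normoxia array 1 and hypoxia array 5 (up to 0.116) and with SAM (0.0667).

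**Figure D3:**
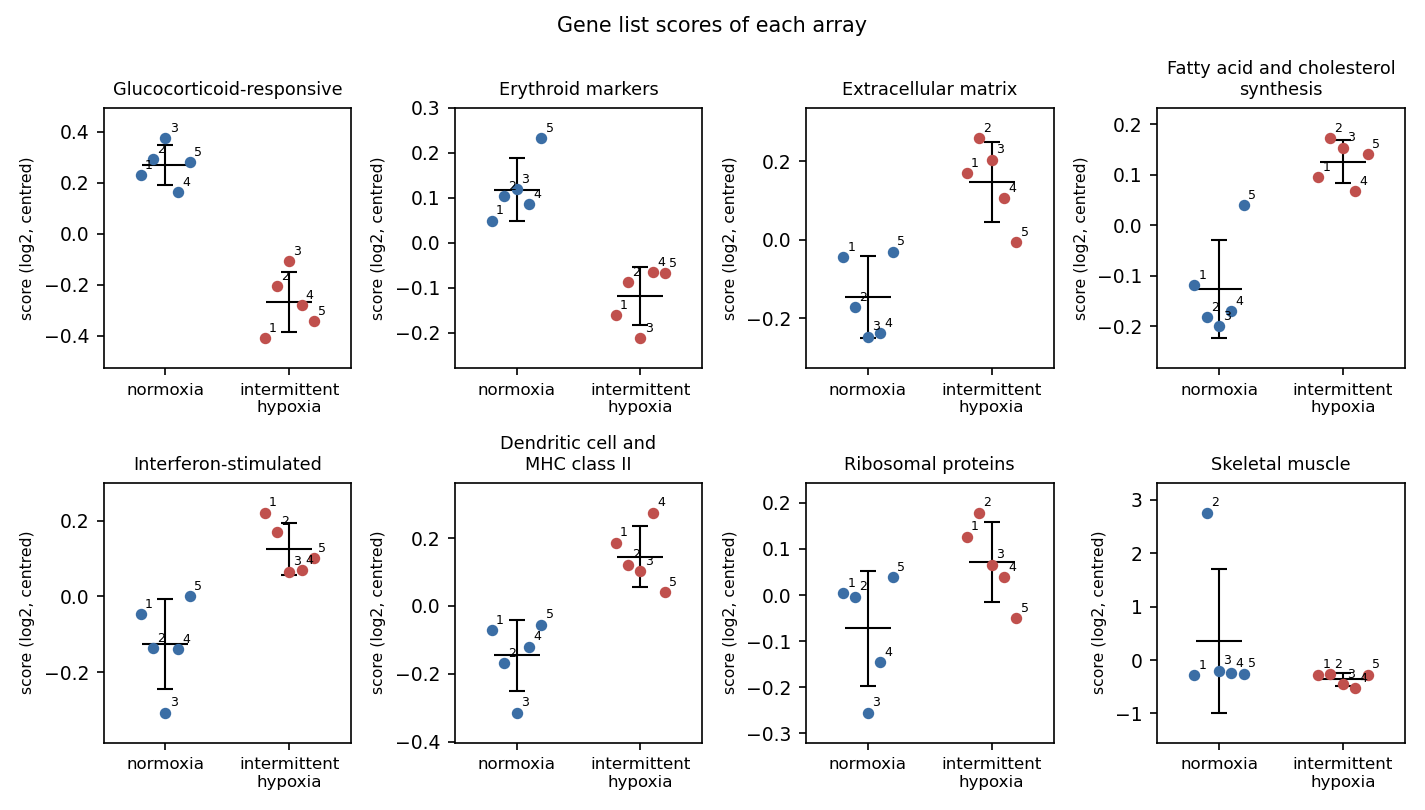
Score of 8 gene lists on each array (vertical axes, mean of the members' log2 values after centring each gene over the 10 arrays), with replicate numbers and mean ± SD in black. The groups are apart in the first 6 panels, overlap for ribosomal proteins, and in skeletal muscle normoxia array 2 stands alone at 2.76.

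Structural genes of the extracellular matrix were higher after intermittent hypoxia. Of 39 measured members 16 rose and 2 fell, and 27 and 4 passed when adjusted over the list alone. The elastic fibre genes Mfap5 and Loxl1 rose by 0.85 (SE 0.10) and 1.02 (SE 0.12), the second being a 2.03-fold increase in a crosslinking enzyme. The collagen genes Col6a3 and Col1a1 rose by 0.67 (SE 0.09) and 0.80 (SE 0.12). The other probe set of Col1a1 differed by 0.22 and did not pass. The list's median was 0.30, and camera gave an adjusted p of 1.1e-06, against an adjusted p = 0.561 with an estimated correlation. Markers of lung fibroblasts, the main source of such matrix, rose in 6 of 21 cases and in 7 when adjusted over the list alone. Examples were Gyg (0.96, SE 0.14), Col14a1 (0.60, SE 0.10), Col13a1 (0.75, SE 0.13) and Macf1 (0.45, SE 0.09). The other probe set of Col14a1 differed by 0.22 and did not pass. The fibroblast list had a camera adjusted p of 0.00321, against an adjusted p = 0.610 with an estimated correlation. The lower matrix scores of normoxia arrays 2, 3 and 4, from -0.25 to -0.17, stood beside -0.04 and -0.03 on normoxia arrays 1 and 5. Without arrays 2 to 4 the median of the matrix list was 0.19, against 0.30 with all arrays. Its camera adjusted p was then 2.0e-06 with the preset correlation and 2 normoxia arrays left. The same test called a median of 14 lists in other splits of the arrays, so this p cannot show that the shift stands without these arrays.

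Genes for proteases and growth of the alveolar wall changed singly, without a shift of their lists. Adamts1, a matrix protease, rose by 0.79 (SE 0.14) and the inhibitor gene Timp4 fell by 0.66 (SE 0.10). The other probe set of Timp4 differed by -0.01 and did not pass. Of 22 protease genes 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.572). Of 36 growth factors and morphogens 6 rose and 1 fell (8 and 1 when adjusted over the list alone, camera adjusted p = 0.223), with Tgfb3 at 0.40 (SE 0.07) and Tgfb2 at 0.35 (SE 0.07). Emcn, which encodes the endothelial surface protein endomucin, rose by 1.03 (SE 0.08) or 2.04-fold, and Cd34 rose by 0.68 (SE 0.09). These were 2 of the 3 endothelial markers that rose, beside 2 that fell, of 24 (5 and 2 when adjusted over the list alone, camera adjusted p = 0.123), and without normoxia array 5 the list passed (0.0462). Pdgfb, the growth factor that draws pericytes to vessels, rose by 0.79 (SE 0.09). It and Aplnr were the 2 of 25 angiogenesis genes that passed, both higher (3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.133). Of 36 cell cycle genes 1 passed, Rrm2, which fell by 0.37 (SE 0.08), 1 passed when adjusted over the list alone, and camera gave an adjusted p of 0.243. Of 2 other probe sets of Rrm2 neither passed, and the mean of the 3 did not pass either (adjusted p = 0.0870). Of 18 smooth muscle and pericyte markers 1 rose and Rgs5, a pericyte gene, fell by 0.63 (SE 0.14) (1 and 1 when adjusted over the list alone, camera adjusted p = 0.467).

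Targets of the hypoxia-inducible factors showed no common shift. Of 28 members 1 rose and 3 fell, and 2 and 4 passed when adjusted over the list alone, with a camera adjusted p of 0.545. Bhlhe40 was the member that rose and Ddit4 had the largest fall. Quantile normalization gave this list a lower call, with an adjusted p of 0.0156, and so did the arrays without normoxia arrays 2 to 4 (0.0388). Of 16 glycolysis genes 3 rose and 1 fell (4 and 1 when adjusted over the list alone, camera adjusted p = 0.989). Of 30 antioxidant genes 2 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.941), among them the metallothionein gene Mt2, which fell by 0.48 (SE 0.10). Of 29 heat shock and unfolded protein genes 2 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.489). Of 15 iron and haem genes 1 rose, also when adjusted over the list alone (adjusted p = 0.566), and of 24 immediate-early genes 2 rose, also when adjusted over the list alone (adjusted p = 0.393, and 0.0441 without hypoxia array 2). Among 19 retinoid genes 1 rose and none did when adjusted over the list alone (adjusted p = 0.624). Of 26 genes of vascular tone 4 fell (3 higher and 5 lower when adjusted over the list alone, adjusted p = 0.0761), and the list passed as lower without normoxia array 4 (0.0488) or hypoxia array 2 (0.0441) and without normoxia arrays 2 to 4 together (0.0101).

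Lipid synthesis genes were higher as a group. Of 21 members of the fatty acid and cholesterol list 10 rose and 1 fell, and 13 and 1 passed when adjusted over the list alone. Sqle, which encodes squalene epoxidase, rose by 0.51 (SE 0.07), Msmo1, another enzyme of the sterol pathway, by 0.68 (SE 0.11), Srebf2, the transcription factor that controls the pathway, by 0.42 (SE 0.07), and the sterol carrier gene Stard4 by 0.52 (SE 0.09). The median was 0.27, and camera gave an adjusted p of 0.00012, against an adjusted p = 0.397 with an estimated correlation. Genes of fatty acid oxidation and PPAR targets had 4 falls and no rise among 20 members (1 higher and 5 lower when adjusted over the list alone), including Angptl4 and Ppara, a fatty acid receptor gene that fell by 0.50 (SE 0.11). The camera adjusted p of this list was 0.0758, and with quantile normalization it passed as lower at 0.00215. It also passed without normoxia array 2 (0.0379), 3 (0.0371) or 4 (0.0231) and without hypoxia array 1 (0.0178), 2 (0.0164) or 3 (0.0291), but its adjusted p was 0.349 without normoxia array 5. The list's median was -0.04 with all arrays and ran from -0.09 to 0.04 with 1 array left out. Without normoxia arrays 2 to 4 together its median was -0.15 and its adjusted p 3.6e-05, and it passed with only probe sets at or above the median level (0.00930) and with the mean of a gene's probe sets (0.0247). Adipose transcripts moved the same way, as given above. All 40 genes of oxidative phosphorylation had a positive change, with a median of 0.14, though 3 rose and none passed when adjusted over the list alone. Camera gave an adjusted p of 0.000426, against an adjusted p = 0.659 with an estimated correlation. Of 29 ribosomal protein genes none passed over all genes or when adjusted over the list alone, 28 had a positive change, and the median was 0.16. Their camera adjusted p was 0.00274, against an adjusted p = 0.659 with an estimated correlation. Both lists lost the call, and most of the shift, with quantile normalization (medians of 0.01 and 0.05, adjusted p of 0.620 and 0.0901) and without normoxia arrays 2 to 4 (medians of 0.01 and 0.03, adjusted p of 0.525 and 0.183).

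The lists of dendritic cell and MHC class II genes, interferon-stimulated genes and B and plasma cell markers were higher after intermittent hypoxia. Of 17 dendritic cell and MHC class II genes 7 rose, and 8 when adjusted over the list alone. The class II genes H2-DMa, H2-Eb1 and Cd74 rose by 0.93 (SE 0.15), 0.61 (SE 0.13) and 0.64 (SE 0.13). The list's camera adjusted p was 0.00267, against an adjusted p = 0.465 with an estimated correlation. Of 28 interferon-stimulated genes 10 rose and 1 fell, and 15 and 3 passed when adjusted over the list alone. Ifit2 rose by 0.68 (SE 0.11) and Rtp4 by 0.40 (SE 0.07), whereas the antiviral gene Rsad2 fell by 0.70 (SE 0.12). The other probe set of Rtp4 differed by 0.03 and did not pass. Camera gave the interferon list an adjusted p of 0.00203, against an adjusted p = 0.561 with an estimated correlation. Of 17 B and plasma cell markers 6 rose and 1 fell (9 and 1 when adjusted over the list alone), with Blk at 0.54 (SE 0.09) and the antigen receptor gene Cd79a at 1.01 (SE 0.20). The B cell list had a median of 0.35 and a camera adjusted p of 0.0183, against an adjusted p = 0.623 with an estimated correlation. It lost its call without normoxia array 1 (adjusted p = 0.0506) or hypoxia array 4 (adjusted p = 0.0642), and the score of hypoxia array 4, at 0.51, was the highest of all arrays.

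The T cell, macrophage, monocyte, NF-kB and thymus lists did not pass. Of 24 T and NK cell markers 6 rose, among them Cd3d by 0.49 (SE 0.09) (7 when adjusted over the list alone, camera adjusted p = 0.0989), and the list passed as higher with quantile normalization (0.0130), without normoxia array 4 (0.0231) or hypoxia array 2 (0.0165), and without normoxia arrays 2 to 4 together (0.000955). Of 15 alveolar macrophage markers 3 rose and 1 fell (6 and 2 when adjusted over the list alone, adjusted p = 0.0877), with Cd68 at 0.74 (SE 0.13), and this list passed without hypoxia array 5 (0.00424) and without normoxia arrays 2 to 4 together (0.0467). Of 18 monocyte and interstitial macrophage markers 3 rose and 1 fell (5 and 1 when adjusted over the list alone, adjusted p = 0.0989). The scavenger receptor gene Cd163 fell by 0.62 (SE 0.12). Of 29 genes of NF-kB and acute inflammation 4 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.930), with the adhesion molecule gene Icam1 at 0.53 (SE 0.10). Thymus and lymphoid genes had 1 rise and 1 fall among 12, also when adjusted over the list alone (adjusted p = 0.191).

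With all arrays and camera's preset correlation, lists of alveolar epithelial markers were slightly higher, a shift that rested largely on normoxia arrays 2 to 4. Of 13 alveolar type 1 markers 5 rose (6 when adjusted over the list alone), led by the water channel gene Aqp5 at 0.53 (SE 0.10). This list's camera adjusted p was 0.00302, against an adjusted p = 0.623 with an estimated correlation. Of 17 alveolar type 2 markers 3 rose (4 when adjusted over the list alone), of which Cd74 is also an MHC class II gene and lies on that list too, while the surfactant gene Sftpc differed by -0.01 (adjusted p = 0.942), a member named after its value was seen. Camera gave the type 2 list an adjusted p of 0.0262, against an adjusted p = 0.659 with an estimated correlation. The type 2 call was lost without normoxia array 2 (adjusted p = 0.0557), normoxia array 3 (0.0560) or hypoxia array 3 (0.0584). Of 9 mesothelial markers 2 rose (3 when adjusted over the list alone), including Gpm6a at 0.41 (SE 0.07), whose call quantile normalization ended (0.25, adjusted p = 0.0566). Their camera adjusted p of 0.0468, an adjusted p = 0.610 with an estimated correlation, was lost without any of 6 single arrays, normoxia arrays 1, 2 and 4 and hypoxia arrays 3, 4 and 5, at up to 0.0887. Without normoxia arrays 2 to 4 the type 1, type 2 and mesothelial lists had medians of 0.06, -0.01 and 0.04. Against these stood medians of 0.21, 0.14 and 0.16 with all arrays. Their camera adjusted p values were then 0.119, 0.950 and 0.323. Quantile normalization also ended these 3 calls, as given below. Club and secretory cell markers were lower. Of 15 members 4 fell (6 when adjusted over the list alone), Ltf being the largest, and the main club cell product Scgb1a1, named after its value was seen, differed by -0.01 (adjusted p = 0.918). Their camera adjusted p was 0.000551, against an adjusted p = 0.394 with an estimated correlation. Of 11 ciliated cell markers 1 rose (2 when adjusted over the list alone), with a median of -0.03, a mean of 0.01 and a camera adjusted p of 0.862. Of 9 nerve and Schwann cell genes 3 rose and 1 fell, also when adjusted over the list alone, with a median of -0.05, a mean of 0.08 and an adjusted p of 0.862.

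Blood cell transcripts, which a whole lung holds in its vessels, were lower in part. Erythroid markers had 2 falls among 22 members, also when adjusted over the list alone. The anion exchanger gene Slc4a1 fell by 1.03 (SE 0.15) to 0.489 of its normoxia level, and of its 2 other probe sets 1 dropped by 1.96 (adjusted p = 8.5e-08) and 1 had a change of 0.07. Bpgm fell by 0.49 (SE 0.13), and lost its call without any of 6 single arrays, normoxia arrays 2 and 4 and hypoxia arrays 1 to 4 (adjusted p up to 0.0771), with SAM (0.0576) and with the mean of its probe sets (0.116). The globin gene Hba-a1, named after its value was seen, differed by -0.06 (adjusted p = 0.537). The erythroid camera adjusted p was 0.00012, against an adjusted p = 0.211 with an estimated correlation. Among 13 platelet markers 2 fell and Thbs1, which many other cells express, rose, and 9 were lower and 1 higher when adjusted over the list alone. Their camera adjusted p was 0.00267, against an adjusted p = 0.610 with an estimated correlation. Of 18 neutrophil markers 2 fell, Ltf among them, and 1 rose (5 and 1 when adjusted over the list alone). Camera gave an adjusted p of 0.0068, against an adjusted p = 0.623 with an estimated correlation, and without normoxia arrays 2 to 4 the neutrophil list had an adjusted p of 0.142. Of 15 mast cell, basophil and eosinophil markers 2 fell, also when adjusted over the list alone. Their adjusted p of 0.0262, an adjusted p = 0.610 with an estimated correlation, became 0.0824 without normoxia array 3, and the median turned from -0.11 to 0.03 without normoxia arrays 2 to 4.

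Muscle transcripts set a single array apart. Skeletal muscle genes had a median change of -0.69 and a camera adjusted p of 0.00437, against an adjusted p = 0.659 with an estimated correlation. Of 19 members 1 fell, Casq1, and none when adjusted over the list alone. On normoxia array 2 the list score was 2.76, while the other 9 arrays lay between -0.52 and -0.20. Without that array the median was -0.05 and the adjusted p 0.0766. Of 25 cardiac muscle genes 1 fell and none when adjusted over the list alone, with an adjusted p of 0.0834, which fell below the threshold without normoxia array 1 (0.0477), hypoxia array 1 (0.0186) or hypoxia array 5 (0.0285), with only probe sets at or above the median level (0.0164) and with arrayWeights (0.0459). Without hypoxia array 4 it was 0.814. That array had a cardiac score of -0.44, while the other hypoxia arrays lay between 0.003 and 0.11. With 1 array left out the cardiac median ran from -0.11 to 0.04.

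Of the 43 tested lists, fixed before the data were examined, 19 passed with camera's preset correlation, 11 higher and 8 lower. With the same test, 99 other splits of these arrays into 5 and 5 called a median of 14 lists and at most 20. None passed with an estimated correlation, and fry called 10 of the 43, not the oxidative phosphorylation, platelet, ribosomal, type 1, skeletal muscle, neutrophil, B cell, mast cell and type 2 lists. With only probe sets at or above the median level, the oxidative phosphorylation, ribosomal, type 1, fibroblast, neutrophil, B cell, type 2 and mesothelial lists lost their calls, at adjusted p values from 0.0613 to 0.288. Quantile normalization ended those of the type 1 (0.0706), skeletal muscle (0.0601), mast cell, type 2 and mesothelial lists (0.181 each). In an exact two-sided permutation test of the list scores, added after the data were seen, 18 lists had an unadjusted p below 0.05 and none passed after adjustment. There 6 lists reached the smallest p that 5 against 5 arrays can give, 0.00794 (adjusted p = 0.0569), which were the glucocorticoid, matrix, erythroid, lipid synthesis, interferon and MHC class II lists.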

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

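The tests of the narrow spread for the glucocorticoid and clock genes, of the time of day, and both tests of the muscle genes were chosen only after the results were seen. Of 252 groups of 5 values tested for 1 array standing apart, 17 met the rule. Chance flags about 1 in 20 groups, or 12.6 here, so most of the single genes below need no explanation. Each value in the next sentences is the gap of that array to the nearest of its group, as a share of the group's whole range.

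Skeletal muscle transcripts stood apart on normoxia array 2, where the list score was 2.76 (gap 0.973), with gaps of 0.967 for Myh1, 0.923 for Tnnc2 and 0.824 for Acta1, 3 abundant muscle genes named after their values were seen. Of 19 members 18 had their highest value of all arrays there, and Myh1 lay 7.16 above the mean of the other 9 arrays on the log2 scale. The narrow spread that array 2 shares with normoxia arrays 3 and 4 was argued against as the cause, since the list score of those arrays lay at most 0.133 above the mean of the other 7. Skeletal muscle attached to that sample may account for it, a hypothesis formed from the same values. No biological explanation was tested, because the array belongs to the normoxia group with 4 others that lacked the signal.

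The number of changed probe sets depended on which normoxia arrays were kept: with 2 of the 5 left, the 3 pairs from within normoxia arrays 2 to 4 gave 3466 to 6255 and the other 7 pairs 12 to 160, the pair without arrays 2 to 4 giving 16 and the pair without arrays 1, 3 and 4 giving 12, so having fewer arrays may account for part of that drop. Only 1 of 100 splits of the arrays into 5 and 5, the real one, called as many as 2699 probe sets, and the highest other called 1758. That share is under the 0.05 set beforehand, which argues against chance for this count over all drawn splits without excluding it. For the 19 lists chance was not argued against, as 6 of 100 splits called as many, the others had a median of 14 and the highest other called 20. The 2 other splits with over 2 calls (1758 and 705) kept normoxia arrays 2 to 4 on 1 side. Over all 14 other drawn splits that did so, however, the median was 0 calls. The splits with 1758 and 705 calls differed from the real one only by exchanging normoxia array 5 or 1 with hypoxia array 5. With the real one, only 15 drawn splits kept normoxia arrays 2 to 4 on 1 side, too few for a share under 0.05 among them. Probe sets called between normoxia arrays 2 to 4 and 3 hypoxia arrays kept a median share of 0.304 of their change between normoxia arrays 1 and 5 and the other 2 hypoxia arrays, from 0.0978 to 0.480 over 10 choices. That share lies between the bounds set for a purely technical and for a shared difference, so the narrow spread of these 3 arrays and the exposure cannot be told apart for the count as a whole.

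Glucocorticoid-responsive genes were lower with camera's preset correlation, though not with an estimated one (adjusted p = 0.0596) or in the adjusted exact permutation test (0.0569), and 7 clock genes passed in both directions while their list did not (0.0655). The narrow spread was argued against as the whole cause: without normoxia arrays 2 to 4 the glucocorticoid list's median was 1.07 times that with all arrays, and the changes of the 7 clock genes were a share of 0.730 or more of those with all arrays, although only Nr1d1 and Cry1 still passed and Dbp (0.251), Per2 (0.381) and Bhlhe40 (0.133) did not. Overlap with other lists was argued against too, as the 11 glucocorticoid members on none of the lists compared had a median of -0.47, all with a negative change and 7 of them passing, and camera on these 11 alone gave an unadjusted p of 1.6e-09 with the preset and 0.000405 with an estimated correlation. Genes in phase with Nr1d1 and genes of the opposite phase differed by 0.35 in their median change, and by 0.53 without normoxia arrays 2 to 4, but the first set went both ways (Nr1d1 2.29, Hlf -0.48), so a different hour of tissue collection in the 2 groups, which the labels do not give, and a shift of the clock or of hormone rhythm by the exposure itself cannot be told apart. The exposure may lower glucocorticoid signalling, but hormone levels were not measured and this stays untested.

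The other values are given without an explanation. Hypoxia array 4 stood apart in 3 list scores, high for NF-kB and acute inflammatory genes (0.823) and for neutrophil markers (0.876) and low for cardiac muscle genes (0.806). Normoxia array 4 was low for heat shock genes (0.789). Normoxia array 5 was high for Bpgm (0.745) and Col13a1 (0.811) and low for Hlf (0.783), and normoxia array 3 was low for Blk (0.807). Hypoxia array 1 was high for Gbp6 (0.736) and Gyg (0.715) and low for Cd163 (0.711). Hypoxia array 2 was high for Macf1 (0.854), and hypoxia array 3 was low for Acta1 (0.906).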

How the results depend on the processing

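The alternatives without normoxia arrays 2, 3 and 4 and the exact permutation of list scores were chosen after the results were seen. No called gene or list passed in the opposite direction under any alternative run, but without normoxia arrays 2, 3 and 4 the medians of the mast cell list (-0.11 to 0.03) and the type 2 list (0.14 to -0.01) changed sign, both no longer passing. SAM called 2005 probe sets, 1909 of them also called by limma. Quantile normalization called 2285, of which 1891 were shared, and kept 87 of 109 named calls and 12 of 19 lists.

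Counts differed by over 1.5 times under several choices. With a replicate block 1755 probe sets changed, 1274 higher and 481 lower, and the clock (0.0228) and fatty acid oxidation lists (0.0442) also passed. The replicate numbers gave no clear sign of pairing, as deviations of arrays with the same number correlated between -0.24 and 0.22. Of 10 arrays 4 correlated best with their own number, and with so few arrays this check cannot exclude a pairing. With arrayWeights 4132 changed, 1411 of them lower. The lowest weight was that of normoxia array 5 (0.554), and leaving that array out gave 4800. Whether its low weight caused the rise was not tested. An adjusted p below 0.10 is a wider threshold and gave 4954, 3184 higher and 1770 lower. The mean of all probe sets of a gene gave 1605 genes, 1140 higher and 465 lower, which counts genes rather than probe sets and compares with 1107 higher and 446 lower from 1 probe set per gene. Probe sets at or above the median level gave 492 lower ones and 12 lists, with fewer features tested.

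Leaving out 1 array gave 1003 to 4800 changed probe sets, 748 to 3094 higher and 255 to 1706 lower, in each case lowest without normoxia array 4 and highest without normoxia array 5. It gave 17 to 24 lists, the lowest without normoxia array 2 or hypoxia array 4 and the highest without hypoxia array 2. Counts were also 1341 and 1123 without normoxia arrays 2 and 3, and 1265, 1383, 1371 and 1714 without hypoxia arrays 1 to 4. Without normoxia arrays 2, 3 and 4 together 16 changed, 7 higher and 9 lower, with 2 normoxia arrays left.

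Of 43 lists camera with an estimated correlation called 0, where the preset correlation called 19 and fry 10. The exact permutation of the list score also called 0 after adjustment, with 18 lists at an unadjusted p below 0.05. Signal over background was not in the table, so dim probe sets were judged by level alone.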
